A study of Mus musculus with 4 samples.

How the data were processed

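The series holds 4 libraries of CD8 T cells from the spleens of adult mice, 1 library in each of 4 groups. Per the labels' protocols, the cells were isolated with magnetic beads against CD8a. For chromatin immunoprecipitation (ChIP), 50000000 cells from 5 mice were frozen, thawed, lysed and sonicated, and the chromatin was captured with a rabbit antiserum against Runx3 at a dilution of 1 in 200. For CUT&RUN, in which an antibody tethers micrococcal nuclease to its target so that only DNA near the target is released, 150000 fresh cells from 1 mouse were bound to beads and treated with the same antiserum at 1 in 200. The other 2 libraries were a whole cell extract of the ChIP material and a CUT&RUN library made with normal rabbit serum. All libraries had 12 PCR cycles, per the labels' protocols. The analysis used 2 peak lists, 1 for each anti-Runx3 library. The whole cell extract entered as the control of the ChIP list, and the normal serum library was not analysed here.

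Per the submitters' processing notes, reads were aligned with Bowtie to mm10 and peaks were called with MACS2. The aligner's version and settings were not given in the sources used here. Per the file headers, MACS2 2.1.1.20160309 was run on paired-end fragments and kept at most 1 fragment per position in both libraries. The ChIP list was called at q of 0.05 against the whole cell extract. The CUT&RUN list was called at q of 1e-05 without a control, on an alignment whose name, per the file headers, refers to nucleosome-free fragments; the length limit was not given in the sources used here. The name of the control alignment in the ChIP header refers to the removal of reads that are not unique, and the name of the ChIP alignment does not. Each library was called on its own.

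The ChIP library had 48285251 fragments, of which 9532996 were left after duplicates were removed, a loss of 80.3%. The CUT&RUN library had 17896991 fragments, of which 14068364 were left, a loss of 21.4%. Of the fragments of the control, a share of 0.09 was redundant. Mean fragment size, per the file headers, was 115 bp in ChIP and 63 bp in CUT&RUN.

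For each peak, the deposited lists give the start, end and summit in mm10 (counted from 1). They give the pileup, a coverage signal that per the file headers counts the fragments over the summit after duplicate removal. They also give −log10 p and −log10 q values and a fold enrichment, the ratio of the summit's pileup to the expected background, all as the authors' peak caller wrote them. In ChIP the expected background could follow the control and the local neighbourhood, but for 97.1% of peaks it was nearly the same value. ChIP folds therefore mostly follow the pileup. In CUT&RUN it came from the 10 kb around each peak of the same library, so the folds of the lists are not alike. Pileup, p, q and fold are each peak's own values. They were used to describe, rank and filter peaks within a list, and a peak's height was not compared between assays. The only use across assays was the ratio of CUT&RUN to ChIP pileup at paired peaks, taken on X relative to the autosomes.

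Peaks were ranked within each list by q, with ties broken by pileup and then by peak number. Peaks of the lists were taken as shared when they overlapped by at least 1 bp (counts checked with bedtools 2.31.1). Shares have exact 95% Clopper-Pearson intervals, and pileups have exact 95% Poisson intervals; both cover counting error only, and fragments amplified by PCR are not independent molecules. Chance overlap was taken from 100 random placements of the other list's peaks on the same chromosome with the same widths. Assembly gaps could not be excluded, since no genome sequence was used here. With 1 library per assay, no test between assays was possible, and no p-value is given. Assay, cell number, freezing, the mice, fragment selection and the peak calling settings all changed together.

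Genes came from a RefSeq table of GRCm38.p6 (mm10) with 49939 genes on chromosomes 1 to 19, X and Y, 21883 of them protein-coding. The table gives gene spans without strand or exons. The planned share of summits at transcription start sites was therefore replaced by the share of summits within 1 kb of either end of a gene, called a gene edge here, and the planned motif results were not made. A gene counted as occupied when a summit lay in its span extended by 10 kb on each side. The 19 gene lists were fixed before the data were examined, with 304 entries. Of these, 303 matched the table (Tf through the synonym Trf, with no match for Ahsp), and 302 were tested, since the table calls Zfp683 a pseudogene. Some genes stood in more than 1 list, so the tested entries held 294 distinct genes. Each list's number of occupied members was set beside 10000 random lists of protein-coding genes of the same size, matched on gene length in 20 bins. Random lists hold silent genes and were not matched on expression or on how close their members lie. Neighbouring members of a list can be counted from the same peak. The share of random lists with as many occupied members describes these libraries and is not a p-value.

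The genes named in the text follow a rule fixed before the data were examined. It names Runx3, Runx1, Cbfb, Cd8a, Cd8b1, Cd4 and Zbtb7b, and from each list up to 4 members with the best ranked peaks and those without a peak in either list. It also names the nearest protein-coding gene to the 10 best ranked peaks in both lists, in ChIP only and in CUT&RUN only, on chromosomes 1 to 19 and X. Distance to a gene edge replaced distance to a start site in this rule, and some genes that meet it are not reported here. Other genes named for an extreme or a missing value were chosen after their values were seen, and this is said where they appear.

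The background behind each peak was worked out from the deposited pileup and fold as (pileup + 1) / fold − 1. For 97.1% of ChIP peaks it lay within 0.1% of the list's median. Peaks with over 3 times that median, and any peak within 5 kb of them, are called high-background regions here. This definition was made after seeing the data, and it removed, with unplaced contigs, Y and mitochondrial peaks, 254 ChIP and 397 CUT&RUN peaks in the alternatives that use it. Alternatives fixed before the data were examined changed the overlap rule, the peak width, the number of peaks, the chromosomes and the gene window. Those on gene edges, on high-background regions and on ChIP peaks at q of 1e-05 or less were added after seeing the data.

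The overlap, distance and gene counting steps were tested on simulated data. In a simulated copy of the ChIP list of 13050 peaks, 100% of the planted shared peaks were recovered and 0.123% of the others overlapped by chance. The planted peaks were ChIP peaks moved by a short distance with their widths kept, so their recovery checks only the counting. All 300 gene edge distances and the counts of all 1374 genes of chromosome 19 equalled a direct count. Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.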

Results

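Runx3 is a transcription factor of the RUNX family that is needed for the development of CD8 T cells. Its binding across the genome was mapped in splenic CD8 T cells of adult mice by ChIP and by CUT&RUN, with the same antiserum and 1 library per assay. The files gave 13166 ChIP peaks from 9532996 fragments and 15891 CUT&RUN peaks from 14068364 fragments after duplicate removal. ChIP peaks had a median width of 261 bp (quartiles 176 and 385 bp) and covered 4.25 Mb. CUT&RUN peaks had a median width of 147 bp (quartiles 98 and 212 bp) and covered 2.67 Mb. There were no replicates, so differences between the assays have no replicate check.

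The design asks which regions Runx3 occupies in CD8 T cells and how far the maps from the assays overlap. Both assays placed strong peaks at genes of T cell identity. At Cd3d, which encodes a chain of the CD3 complex, the ChIP summit at chromosome 9, 44986670 had a pileup of 88 fragments (95% interval 70.6 to 108) and ranked 18 of 13166, and the CUT&RUN summit at 44986693 had a pileup of 131 (110 to 155) and ranked 234 of 15891. At Ptprc, which encodes CD45, the summits at chromosome 1, 138136611 and 138136612 lay 1 bp apart inside the gene, with ranks of 47 and 115. Runx3 itself carried a peak of rank 45 in ChIP and 96 in CUT&RUN.

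Of the 13166 ChIP peaks, 8721 (66.2%, 95% interval 65.4 to 67) overlapped a CUT&RUN peak, against a mean of 0.476% with randomly placed CUT&RUN peaks (highest of 100 placements, 0.615%). Of the 15891 CUT&RUN peaks, 9345 (58.8%, 58.0 to 59.6) overlapped a ChIP peak, against 0.590% with random placement (highest, 0.957%). Summits of overlapping pairs lay a median of 36 bp apart (quartiles 16 and 71 bp), and 62.7% lay within 50 bp. Overlap followed rank in both lists. It fell from 96.4% (95.2 to 97.3) of the top 10% of ChIP peaks to 30.2% (27.8 to 32.8) of the weakest, and from 91.1% (89.6 to 92.4) to 28.9% (26.7 to 31.2) of CUT&RUN peaks. Shared ChIP peaks had a median pileup of 14 against 9 for ChIP peaks without overlap, and shared CUT&RUN peaks had 33 against 18. The lists were called at different q thresholds. With ChIP peaks at q of 1e-05 or less, 81.5% of the 7909 that remained overlapped a CUT&RUN peak, and 44.3% of CUT&RUN peaks overlapped one of them.

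**Figure D1:**
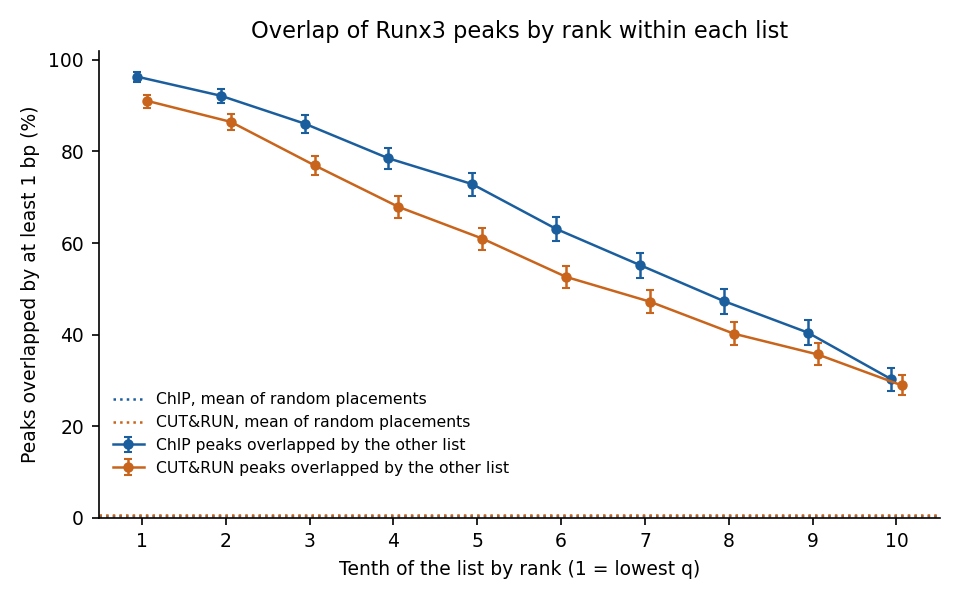
Share of Runx3 peaks (y axis, percent) that overlapped a peak of the other list by at least 1 bp, in 10 rank bins of the ChIP and CUT&RUN lists (x axis, 1 is the strongest); bars are exact 95% binomial intervals and dotted lines are means of random placements. Overlap fell from 96.4% to 30.2% in ChIP and from 91.1% to 28.9% in CUT&RUN, with random means of 0.476% and 0.590%.

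The Runx3 gene (chromosome 4, 135120645 to 135177990) had its strongest peak in both assays just outside 1 edge of the gene. The ChIP summit at 135120525, 0.12 kb outside, had a pileup of 58 (44.0 to 75) and a fold of 27.8 over background, and the CUT&RUN summit at 135120440 had a pileup of 180 (155 to 208) and a fold of 29.6. A weaker peak inside the gene appeared in both lists, at 135157499 in ChIP (pileup 10, 4.80 to 18.4) and 135157535 in CUT&RUN (pileup 20, 12.2 to 30.9). Runx1, another RUNX gene, held 7 ChIP peaks, all of which overlapped CUT&RUN peaks, and 11 CUT&RUN peaks. Its best ChIP peak, at chromosome 16, 92801768, had a pileup of 29 (19.4 to 41.6), and its best CUT&RUN peak, at 92641257, had a pileup of 94 (76.0 to 115). Cbfb, the gene of the partner subunit of RUNX proteins, had weak peaks near 1 edge, with pileups of 9 and 10 in ChIP and 16 in CUT&RUN.

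The genes of the CD8 coreceptor, Cd8b1 (chromosome 6, 71322788 to 71337492) and Cd8a (71373427 to 71379171), lie next to each other. In the region that spans both and 10 kb on each side, each assay had 9 peaks, and 5 of each list overlapped the other. In ChIP, 8 of the 9 summits lay in the stretch between the genes, from 71339589 to 71369621, and none lay in a gene span. The highest was at 71342973, with a pileup of 20 (12.2 to 30.9). CUT&RUN had its highest peaks at 71357701 (pileup 42) and 71369583 (pileup 41, 29.4 to 55.6), both shared with ChIP. Only CUT&RUN had peaks just outside a gene edge, at 71322600 near Cd8b1 (pileup 34, 23.5 to 47.5) and at 71373367 near Cd8a (pileup 27, 17.8 to 39.3).

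**Figure D2:**
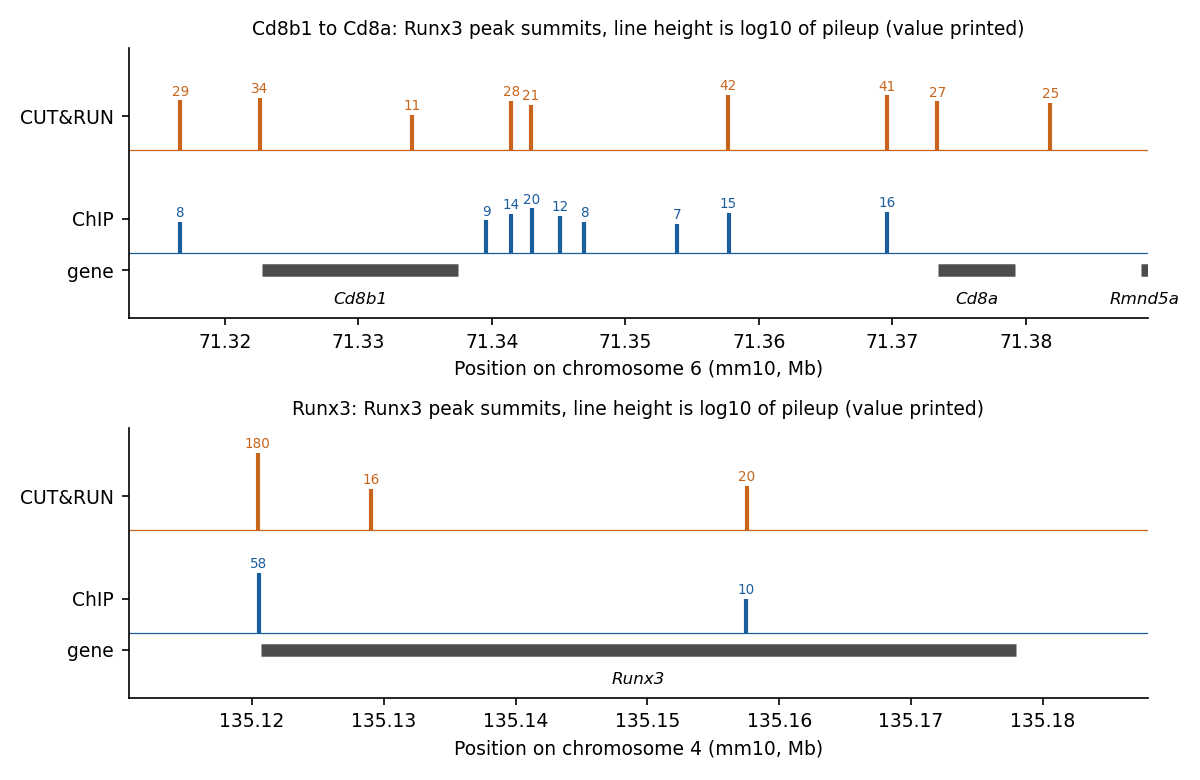
Runx3 peak summits of the ChIP and CUT&RUN lists along the Cd8b1 to Cd8a region and the Runx3 gene (x axis, position in Mb, mm10); each vertical line is a summit, its height is the log10 of the authors' pileup and the pileup in fragments is printed above it. Each assay had 9 peaks in the Cd8 region, and the Runx3 summits with pileups of 58 and 180 lay just outside the left edge of the gene.

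Cd4, the gene of the other coreceptor, had 2 peaks inside the gene in each assay, and both pairs overlapped. The stronger pair lay at chromosome 6, 124886158 in ChIP (pileup 14, 7.65 to 23.5) and 124886113 in CUT&RUN (pileup 80, 63.4 to 99.6), about 2.1 kb from an edge. The CUT&RUN peak stood in the top 7.72% of its list and the ChIP peak in the top 37.1%. Cd4 is known to hold an intronic silencer that needs Runx proteins, but the gene table gives no introns, so the peaks were not placed relative to it. Zbtb7b, which encodes the CD4 lineage factor ThPOK, had no ChIP peak and a single CUT&RUN peak, at chromosome 3, 89396231 (pileup 18, 10.7 to 28.4).

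Genes of T cell receptor signalling, cytokine signalling and the naive and memory state were occupied more often than nearly all random lists of genes of similar length. All 24 genes of T cell receptor signalling and T cell identity had a peak in both assays. Random lists had means of 10.9 and 12.3, and none of 10000 reached 24 in either assay. Neighbouring members were counted separately, and Cd3d and Cd3g had the same best peak in each assay. Among 26 genes of cytokine receptors and signalling, 24 were occupied in each assay, also reached by no random list. The best ranked were Il2ra, a chain of the interleukin receptor that T cells induce on activation (ChIP pileup 41, 29.4 to 55.6; CUT&RUN 106, 86.8 to 128), Stat5b, Jak1 and Stat4. Il15ra and Cish had no peak. Of 15 genes of the naive and memory state, 13 were occupied in each assay (0.03% and 0.16% of random lists had as many). Bach2, a repressor that restrains effector differentiation, led this list with 22 ChIP and 17 CUT&RUN peaks, 13 of them ChIP peaks in both lists. Lef1, Ccr7 and Il7r followed, and Id2 and Myb had no peak.

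Of 20 genes of the CD8 lineage and cytotoxic function, 16 were occupied in ChIP and 17 in CUT&RUN, against random means of 7.99 and 9.01 (0% and 0.04% of random lists had as many). The leading genes were Fasl, the ligand that kills through Fas, with a ChIP pileup of 33 (22.7 to 46.3) and a CUT&RUN pileup of 159 (135 to 186), and Prf1, which encodes perforin, with summits 0.054 and 0.057 kb from the gene. Klrd1 and Klrk1, killer cell lectin-like receptors, shared a peak at chromosome 6, 129608595. Gzma and Eomes had peaks only in ChIP, Ifng, Ccl4 and Tbx21 only in CUT&RUN, and Gzmk in neither; these were named after their values were seen, apart from Gzmk. With gene spans alone, 5 and 7 of the 20 were occupied (26.1% and 4.66% of random lists had as many), and with summits within 1 kb of a gene edge 6 and 8 were (34.4% and 17.8%).

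Tissue residency and activation genes were occupied in 11 of 14 cases in ChIP and 12 in CUT&RUN (1.19% and 0.84% of random lists). Cxcr6, a chemokine receptor of resident T cells, led with pileups of 47 (34.5 to 62.5) and 133 (111 to 158), followed by Nr4a3, Batf and Cd69; Itga1 and Ahr had no peak. Inhibitory receptor genes were occupied in 8 of 12 cases in ChIP and 10 in CUT&RUN (13.2% and 2.46%), led by Vsir, Tigit, Tox and Cd160, with no peak at Cd200r1. Chemokine receptor and integrin genes were occupied in 13 and 12 of 16 cases (0.20% and 2.88%), led by Selplg, Ccr7, Itgb7 and Itgb2, with no peak at Itgb1 among others. All 9 genes of the RUNX family and its corepressors were occupied in both assays (0.08% and 0.35%), among them the Groucho family genes Tle5 and Tle4. The CD4 lineage and helper list was occupied in 9 of 15 cases in each assay (13.0% and 24.3%). Tnfrsf4, Cd4, Icos and Cd40lg led it, and the helper cytokine genes Il4, Il13, Il17a and Il21 were among those with no peak. With summits within 1 kb of a gene edge, the residency list fell to 5 and 6 genes (31.8% and 26.0% of random lists), the inhibitory receptor list to 5 and 6 (18.6% and 13.1%), the chemokine receptor list to 5 and 7 (40.2% and 19%) and the CD4 list to 1 and 1 (99.0% and 99.6%). In the stronger 0.5 of each peak list, the chemokine receptor list fell to 7 and 8 (11.4% and 7.74%) and the inhibitory receptor list had 7 and 7 (3.74% and 5.79%); within 50 kb the latter had 12 and 12 (0.46% and 1.01%).

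Housekeeping and apoptosis genes were also occupied more often than most random lists. Of 18 housekeeping genes, 15 were occupied in each assay (0.03% and 0.16% of random lists), with Hsp90ab1, Ywhaz and Actb among the leading genes. Of 16 apoptosis genes, 15 in ChIP and 14 in CUT&RUN were occupied (0% and 0.15%), led by Fasl, Bcl2l1, Fas and Casp8, and Xiap had no peak. In the stronger 0.5 of the CUT&RUN list, housekeeping genes fell to 8 (10.6% of random lists), and at gene edges apoptosis genes fell to 8 in CUT&RUN (7.55%). Cell cycle genes were occupied in 11 of 22 cases in ChIP and 16 in CUT&RUN (32.1% and 1.88%), led by Ccnd3, Cdk4, Cdk2 and Pcna, with no peak at Ccnb1, Ccnb2 and Cdkn2a. Their CUT&RUN count fell to 10 in the stronger 0.5 of the list (9.39%) and to 8 with gene spans alone (10%).

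Markers of other cell types that a spleen preparation could hold were, within 10 kb and with all peaks, in no list occupied more often than 95% of random lists. B cell markers had peaks in 7 of 15 cases in ChIP and 10 in CUT&RUN (47.2% and 11.8% of random lists had as many). Cd72 led them with pileups of 41 (29.4 to 55.6) and 131 (110 to 155), with Pax5 and Pou2af1 also among the leading genes, while Cd79b, Ms4a1, Ebf1 and Blnk had none. Dendritic cell markers had 5 and 7 of 12 (63.0% and 33.9%), led by Itgax, Flt3, Ccr9 and Xcr1, with none at Clec9a, Batf3, Irf8, Siglech and Cd24a. Monocyte, macrophage and neutrophil markers had 3 and 6 of 15 (94.6% and 60.0%), led by Fcgr1, Cd14, Itgam and Mpo. Csf1r, Lyz2, Adgre1, Cebpa, Cebpb, S100a8, S100a9, Ly6g and Csf3r had none. NK cell markers had 5 and 4 of 10 (48.3% and 83.7%), led by Il2rb, Klrb1c, Cd244a and Klre1, with none at Ncr1, Klra8 and Klrc2. Il2rb was also in the cytokine receptor list and Cd244a in the inhibitory receptor list. At gene edges, B cell markers fell to 1 gene in each assay (9.13% and 4.42% of random lists had as few) and dendritic cell markers to 0 and 1 (3.31% and 8.87%). In the stronger 0.5 of the ChIP list, NK cell markers fell to 1 (19% had as few), and in that of the CUT&RUN list dendritic cell markers stayed at 7 (4.13% had as many).

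Erythroid markers were occupied in 3 of 13 cases in each assay (33.6% and 22.8% of random lists had as few), at Klf1, Epor and Tfrc, with none at the globin genes Hbb-bs, Hbb-bt, Hba-a1 and Hba-a2 or at Gata1, Alas2, Tal1, Slc4a1 and Epb42, among others. Hepatocyte and neuronal genes, which spleen cells do not express, were occupied less often than most random lists. Hepatocyte genes had 3 and 4 of 15, and 6.61% and 8.08% of random lists had as few. Fgb, F2 and, in CUT&RUN, Trf were among those with a peak, and Alb, Apoa1, Apob, Ttr, Fga, Serpina1a, Cyp2e1, Tat, Hnf4a, Ahsg and Pck1 had no peak. Neuronal genes had 3 and 4 of 15 (4.83% and 5.96% had as few), at Slc17a7, Camk2a, Slc32a1 and, in CUT&RUN, Tubb3. Snap25, Syt1, Rbfox3, Grin1, Grin2b, Stmn2, Neurod1, Syn1 and Gad1 were among those with none.

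**Figure D3:**
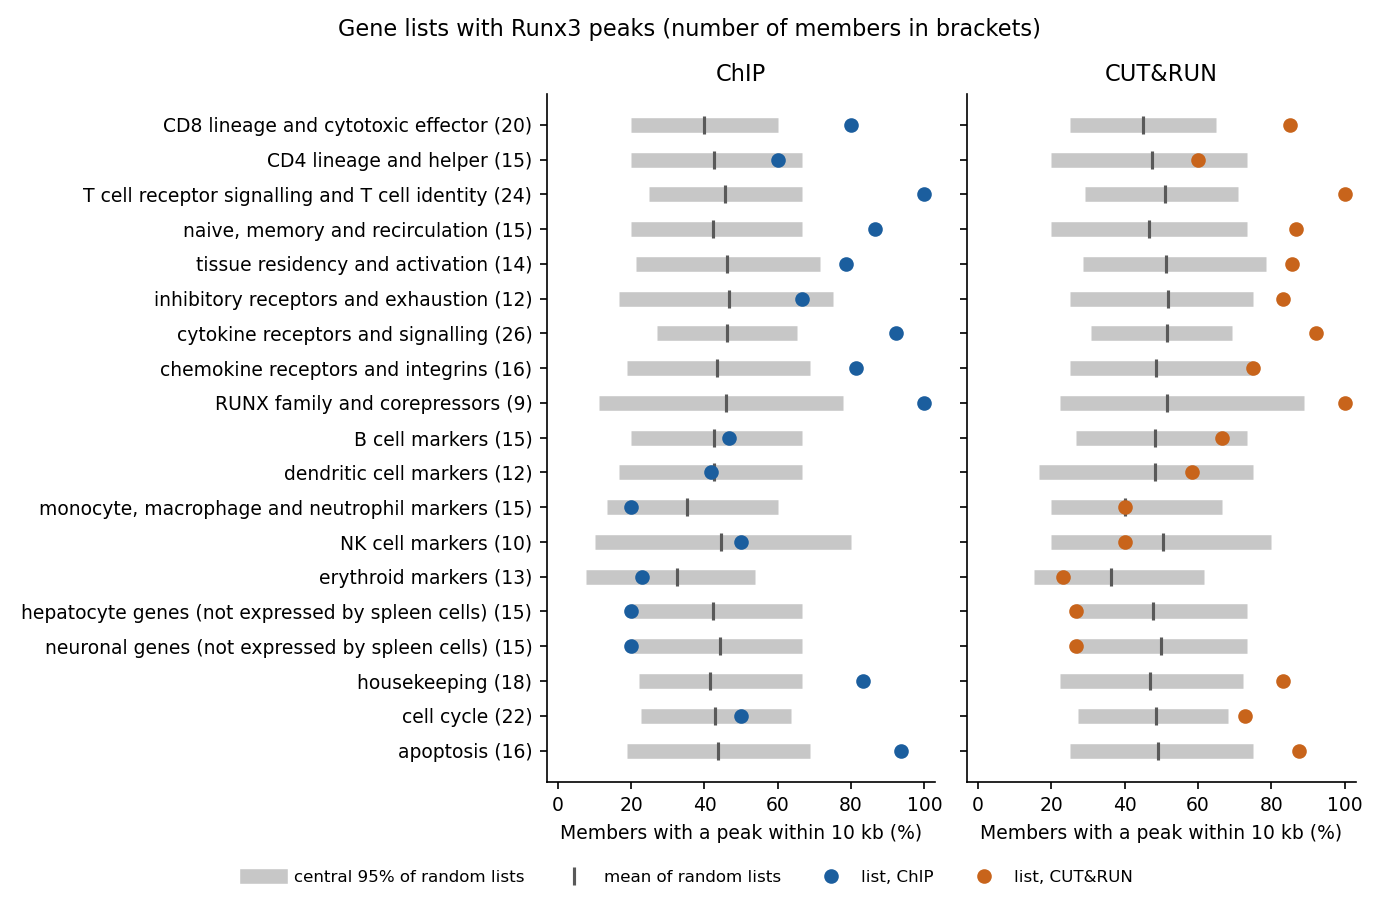
Percent of each list's members with a Runx3 summit in the gene or within 10 kb of it (x axis), for the 19 fixed lists in ChIP and CUT&RUN; dots are the lists, ticks the mean and grey bars the central 95% of 10000 random lists matched on gene length. All 24 genes of the T cell receptor signalling and T cell identity list were occupied in both assays, and neuronal genes were occupied in 3 and 4 of 15 cases.

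The strongest shared peaks of all mostly lay far from genes. Of the 10 best ranked shared peaks, 3 lay about 1 Mb from Lrrc4c on chromosome 2, and another lay inside Chl1. Others had Rpusd4 (29.5 kb away), Gm2244, Rab10, Alkbh8 and Dpy19l2 (14.9 kb away) as their nearest genes. These 9 peaks had ChIP pileups of 778 to 51149, and the background behind them was 199 to 2498 times the list's median. Over the 20 strongest ChIP peaks the median background was 295 times the list's median. The remaining peak lay inside Ppp1r16b, a phosphatase regulator, at chromosome 2, 158719399, with a ChIP pileup of 94 and background at the list's median. Outside high-background regions, the next shared peaks lay nearest to Apol9b, Plaur, Gimap1, Oas3, LOC115488789, Pde3b, Mapk12, Runx3 and Lrch1; with Ppp1r16b, these 10 had ChIP pileups of 51 to 94.

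Of the 10 strongest ChIP-only peaks, 2 lay inside the nearest gene, and the median distance to a gene edge was 57.4 kb; outside high-background regions, where Gm29667, Neto1 and Rorb drop out, 4 of 10 lay inside and the median was 8.09 kb. At Ccdc124 and Dusp2 the summits lay 0.302 and 0.968 kb outside the genes. Others of the top 10 were nearest to Gm29667, Epha5, Gramd3, Neto1, Sag, Rorb and Kifc5b. The strongest CUT&RUN-only peaks were narrow, with widths of 85 to 157 bp (median 102.5 bp, against 363.5 bp in ChIP), and had pileups of 170 to 1223. They were nearest to Pak3, Gm8882, Cdk5rap2, 2210408I21Rik, Sulf1, Olfr854, Dpp9, Pla2r1, Nxph1 and Pou4f1; 3 of the 10 lay inside the gene, and the median distance to an edge was 41.3 kb.

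Runx3 peaks sat at the edges of genes much more often than randomly placed peaks in both assays, and about equally often. The placements were uniform along each chromosome. They do not separate Runx3 binding from signal that gathers at gene edges for other reasons, and the normal serum library was not analysed here. Within 1 kb of a gene edge were 42.3% of ChIP summits (41.5 to 43.2) and 42.5% of CUT&RUN summits (41.7 to 43.2), against random means of 6.49% and 6.46%. Elsewhere inside genes were 38.5% and 38.3%, and between genes 19.2% of each. Shared peaks were at edges in 43.9% of ChIP and 44.0% of CUT&RUN cases, and peaks of 1 list in 39.2% and 40.3%. In the top 10% of each list outside high-background regions, ChIP-only peaks were at an edge in 52.8% of 36 cases (35.5 to 69.6) and shared ChIP peaks in 36.6% of 1231 (33.9 to 39.4). There, CUT&RUN-only peaks were at an edge in 18.1% of 138 cases (12.1 to 25.6) and shared CUT&RUN peaks in 31.5% of 1308 (29.0 to 34.1). High-background regions were defined from the ChIP list alone, so they filter mainly the shared CUT&RUN peaks. An edge is either end of a gene, since the table gives no strand.

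Counted over all 21883 protein-coding genes, 8798 (40.2%, 39.6 to 40.9) had a ChIP peak within 10 kb, 9872 (45.1%, 44.5 to 45.8) had a CUT&RUN peak, and 6896 (31.5%, 30.9 to 32.1) had a ChIP peak that overlapped a CUT&RUN peak.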

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

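Peaks on the mitochondrial genome and on contigs were picked out because the gene comparisons do not use them; the overlap of the full lists counts them. The CUT&RUN list had 19 peaks on the mitochondrial genome and the ChIP list had 0, where a count of 0 among 13166 peaks, with a floor of 3 peaks, allows a share of up to 0.0228%. The ChIP list was called against a control and the CUT&RUN list without one, so these counts are not like for like. The mitochondrial peaks covered 42.9% of the span up to the last position seen and had folds of 1.66 to 3.82. Unplaced or unlocalised contigs held 146 CUT&RUN peaks and 87 ChIP peaks. No group had 4 or more libraries, so no library could be tested against the others of its group.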

How the results depend on the processing

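The alternatives on gene edges, high-background regions and ChIP peaks at q of 1e-05 or less were chosen after seeing the data. Overlap values are the share of ChIP peaks overlapped, then of CUT&RUN peaks, against 66.2% and 58.8%. Requiring 0.5 of the shorter peak gave 63.8% and 56.4%, summits within 200 bp 64.7% and 53.9%, peaks of 400 bp 68.0% in ChIP, the top 2000 of each list 50.3% and 56.2%, both lists at the shorter length 60.5% and 64.4%, the other list extended by 500 bp 70.9% and 63.3%, and ChIP peaks at q of 1e-05 or less 81.5% and 44.3%. Fewer peaks in a list leave fewer partners by construction. At the shorter length and in the top 2000, CUT&RUN had the higher share, the opposite of the full lists. The stronger 0.5 of each list, chromosomes 1 to 19 and X, and the lists without high-background regions stayed within the intervals. The gene edge share, 42.3% in ChIP and 42.5% in CUT&RUN, moved to 53.1% and 52.0% within 2.5 kb, 35.1% and 36.5% within 500 bp, 36.3% and 36.8% with protein-coding genes only, 43.5% and 41.3% in the stronger 0.5 of each list, and 38.7% and 31.1% in the top 2000; in ChIP, any overlap with the window gave 43.9% and q of 1e-05 or less 43.3%. The cause was not tested. Of 38 gene list counts, 17 changed by over 1.5 times with gene spans alone, 12 with 50 kb, 12 in the stronger 0.5, 29 at gene edges, 1 at the shorter length and 0 without high-background regions; of 19 ChIP counts, 2 did at q of 1e-05 or less (NK cell markers 5 to 1, cell cycle 11 to 6). Counts in random lists also change with the gene window and the number of peaks. A changed count therefore need not change how a list stands beside random lists. The planned motif and start site alternatives were not run. No paired analysis was possible because each group has 1 library, so leaving out a replicate was also not possible. The depth of 9532996 ChIP fragments limits weak peaks; the weakest 10% of ChIP peaks had a median pileup of 8.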

Other observations

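The tests of stacked short fragments, of X chromosome copies and ranks, of tRNA genes within 100 bp and of multi-copy reads were chosen after the results were seen, as were all 9 gene families below. The test of multi-copy reads as the source of the strongest peaks was written after their background, 295 times the median, had been seen, so it restates that value; it was left out as a pattern after its result was known, and the X chromosome was taken up in its place after its overlap had been seen. The loci with the most ChIP peaks shared with CUT&RUN were long genes; they are ranked by count without regard to length, and the genes given were picked after the values were seen. Ubac2 (chromosome 14, 142 kb) had 14 shared ChIP peaks and Bach2 (chromosome 4, 348 kb) had 13. Thada had 12, and Foxp1, a transcription factor of T cell quiescence, Prkch, a kinase of T cell signalling, and Ankrd44 had 10 each. Itpkb and Arhgef3 had 9 each.

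Gene families differed in how often they carried a peak at an edge. Of 83 ribosomal protein genes, 50 had a CUT&RUN peak (60.2%, 48.9 to 70.8) and 37 a ChIP peak (44.6%, 33.7 to 55.9). Of 69 histone genes, 35 and 25 did (50.7% and 36.2%). Zinc finger genes named Zfp were about equal, with 115 and 120 of 397. Olfactory receptor genes had a peak in 2 of 1110 cases in each assay. V segments of T cell receptor and antibody genes had a CUT&RUN peak within 500 bp in 51 of 394 cases and a ChIP peak in 25. Protein-coding genes as a whole had 5945 and 5022 of 21883, lncRNA genes 1184 and 1043 of 12727, and pseudogenes 111 and 83 of 9944. CUT&RUN had 3 broad peaks without ChIP overlap in a row at chromosome 1, 24611583 to 24616131, with folds of 3.50 to 4.61.

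Outside high-background regions, 79.2% of the strongest hundredth of CUT&RUN peaks (n = 154, 95% interval 72.0 to 85.3) overlapped a ChIP peak, against 91.8% of the next ranked peaks of the top 10% (n = 1395, 90.3 to 93.2). Low ChIP depth should hide weak peaks first, so no such gap was predicted from it. High-background regions were defined from ChIP peaks alone, so leaving them out removed mostly CUT&RUN peaks that overlapped ChIP. In the top 10% of all CUT&RUN peaks, 1448 of 1590 overlapped ChIP. Of those, outside these regions, contigs, Y and mitochondria, 1308 overlapped and 138 did not. These counts keep the ranks of the full list, and the 154 and 1395 peaks above are a different set. The filter may make part of the gap, and the share without it was not worked out. The test therefore cannot decide on ChIP depth. Within 5 bins of pileup, peaks without overlap had a median width of 0.480 of that of overlapped peaks (range over the bins 0.348 to 0.889). Their narrowness had been seen before this was measured, and narrow peaks have less chance to overlap, so it is no evidence for stacked short fragments or any other cause. The normal serum library was not analysed here, and no biological explanation was tested.

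Transfer RNA genes went the other way from most of the other families. A ChIP summit lay within 500 bp of 89 of 408 tRNA genes (21.8%, 17.9 to 26.1) and a CUT&RUN summit near 44 (10.8%, 7.95 to 14.2), against random means of 0.564% and 0.696%. A general ChIP excess at highly transcribed genes predicted more ChIP than CUT&RUN peaks at ribosomal protein genes. The ratio of ChIP to CUT&RUN there was 0.74, with intervals that met, against 0.845 for all protein-coding genes. No excess was seen there, but those genes were scored within 1 kb of an edge and tRNA genes within 500 bp. The test therefore cannot decide for tRNA genes. The looser ChIP threshold cannot be told apart at 500 bp, where ChIP peaks at q of 1e-05 or less marked 12.7% of the genes, but within 100 bp they still marked 6.13% (4 to 8.91) against 1.47% (0.542 to 3.17) in CUT&RUN. Reads shared between near-identical tRNA copies, loss of such fragments in CUT&RUN and binding of Runx3 or of another protein by the serum may each add to it, and all stay open.

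Outside high-background regions, 33.1% of 302 CUT&RUN peaks on the X chromosome (27.8 to 38.7) overlapped a ChIP peak. The autosomal share was 58.7% (57.9 to 59.5). Of 138 ChIP peaks on X, 71.7% overlapped a CUT&RUN peak, against 66.6% on the autosomes. Autosomal peaks of the same 10 rank bins would give 54.0%. That share was hardly within reach on X, where 302 CUT&RUN peaks met only 138 ChIP peaks. X held 1.07% of the ChIP list and 1.95% of the CUT&RUN list. The comparison therefore cannot decide whether rank adds to the low CUT&RUN share on X. A candidate explanation is that the CUT&RUN mouse had more X copies per cell than the pool of 5 ChIP mice, whose sex the labels used here do not give. At pairs with a single partner, the ratio of CUT&RUN to ChIP pileup on X was 1.14 times that of the autosomes (bootstrap interval 0.955 to 1.26, n = 98), above the range of single autosomes (0.937 to 1.06) but short of the 1.2 set for it. Median pileup at these pairs was lower on X than on the autosomes in both assays (CUT&RUN 27 against 32, ChIP 10 against 13). The higher ratio on X cannot be told apart from chance here. Pairs need a ChIP peak past the threshold, which can pull the X ratio either way.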
